A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

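Targeted RNA libraries of budding yeast were measured by multiplexed primer extension sequencing (MPE-seq), in which pooled primers placed downstream of introns start cDNA synthesis, so that each read shows whether the neighbouring intron had been removed. There were 6 libraries in 2 groups: 3 of the wild type (WT) strain and 3 of the prp2-1 strain, replicates A to C of each. Per the labels, cells grew at 25 °C and were shifted to 37 °C for 15 minutes, and 10 µg of RNA entered each library. The values used are raw counts as deposited by the authors: for each intron and library a count of spliced (mature) reads and a count of unspliced (premature) reads, with no normalization. Per the labels, reads were processed with fastp 0.19.5, HISAT2 2.2.1 and SAMtools against genome build R64. How a read was assigned to spliced or unspliced, and whether duplicates were collapsed, is not given in the sources used here. The authors also deposited a count table made from random draws of 200000, 400000 or 800000 reads per library, with 5 draws at each depth. Its headers for depth and draw were read as interchanged, since the library totals follow the column headed as the seed. Not all reads drawn were counted: counted reads per library averaged 137745, 275571 and 551593 at the 3 depths. The library totals of the full counts given below are counted reads.

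The full table held 309 introns of 298 genes. Intron positions were taken from the coding exons of the R64 annotation for 279 introns, and 30 were not placed. Genes with more than 1 intron were taken to be numbered in the order of transcription. Of the placed introns, 270 started with GT and 277 ended with AG. An intron was tested when its mean of spliced plus unspliced reads over the 6 libraries was at least 10, which left 274 introns of 267 genes and set aside 35. The unspliced percent was the unspliced count over the sum of both counts. Since the sources used here do not state whether molecular identifiers were used, counting intervals and floors cover counting error only. A fold against a group with 0 reads was computed with 3 counts over that group's 3 libraries and is written as a lower bound. This bound leaves out the counting error of the other counts, so an exact interval can reach lower. Other intervals of a fold are exact conditional intervals at 95%, from reads summed over 3 libraries.

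Change of the ratio of unspliced to spliced reads was tested per intron in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test on both counts of each library, with terms for library, read type and the interaction of read type with genotype. The threshold was a Benjamini-Hochberg (BH) adjusted p under 0.05. The log2 change is that interaction, prp2-1 over WT. Total, unspliced and spliced reads per intron were tested the same way without the interaction, each relative to all targeted introns, with library totals and TMM factors of the total reads. Each of these 4 tests covered 274 introns. Medians over introns were compared between groups by exact two-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. Gene lists were compared with the other introns by camera in limma 3.58.1 on log2 ratios with a pseudocount of 0.5, with a preset correlation of 0.01 and, beside it, an estimated correlation. Fry tested whether the introns of a list moved one way. The lists were ribosomal protein genes, meiosis, Mer1-dependent introns, introns of genes that host small nucleolar RNAs, introns under feedback regulation, and ubiquitin and proteasome. The others were cytoskeleton, vesicle transport, RNA processing and export, mitochondrial function, and markers of another cell type or state (a1 and meiotic genes). The lists are short and leave out other targeted genes of the same functions, which count among the other introns in these tests. A list needed 4 tested introns for the set tests. Across introns, Spearman's rho is given without a p, since introns are not independent replicates.

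The introns named include the 8 with the largest and the 8 with the smallest change of the ratio among those past the threshold with no overlap between groups, and a fixed set (ACT1, YRA1, RPL30, RPS14B, DBP2, GLC7, SUS1, TUB1, TUB3, RPL7A, RPL7B, COF1, UBC4, SNR17A, SNR17B and HAC1). They also include the 5 with the largest rise and fall of total, unspliced and spliced reads under the same conditions, and the largest, smallest and median member of each list. This rule, the tests, the lists and most alternatives were fixed before the data were examined. Other introns are named only where a small count is spelled out, and were chosen after their values were seen.

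The library totals ranged from 1612685 to 2671271 reads. Replicates differed by more than counting error, with chi-square per degree of freedom between 33.0 and 118 for pairs of libraries of 1 group. Counts were simulated with the depth and WT unspliced shares of these libraries, but with a fixed dispersion that was not estimated from them. On these counts the ratio test recovered 46.3% of introns changed 2-fold, 95.5% of those changed 4-fold and 97.0% of those changed 16-fold. It called 2.70% of unchanged introns. The test of total reads recovered 83.3% at 2-fold, 100% at 4-fold and called 0.467% of unchanged introns. A simulated list of 12 introns changed 4-fold had a camera p of 9.86e-20, and an unchanged list of 12 had 0.0623. These introns were drawn independently with all others unchanged, unlike in these data. The p values thus do not give the power of camera here.

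Alternatives were DESeq2 1.42.0, limma on log2 odds or on the unspliced fraction, a pseudocount of 5, no minimum, a mean of at least 100 reads, a minimum of 10 unspliced or spliced reads in every library, library totals without TMM, a block for the replicate letter, and leaving out each library in turn. Added after seeing the data were: leaving out introns whose counts differ between the full and the drawn tables, leaving out introns with no spliced read, leaving out HMRA1 and YDR535C, the counts of 1 draw of 800000 reads in place of the full counts, and scaling reads by all 13 tested introns that were over 98% unspliced in WT or, for spliced reads, by 5 of them picked without a set rule. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.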

Results

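Splicing of budding yeast transcripts was measured in WT cells and in the prp2-1 strain, a temperature-sensitive mutant of the spliceosomal ATPase Prp2, which acts before the first catalytic step of splicing. Both groups had 3 libraries. Library totals were 1612685, 1983661 and 2516774 reads for WT replicates A, B and C, and 1845258, 2671271 and 2269285 reads for prp2-1 replicates A, B and C. All positions are on build R64. PRP2 itself has no targeted intron and was not measured.

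The first comparison asked which introns were spliced less completely in prp2-1 than in WT. Unspliced RNA rose relative to spliced RNA in 256 of 274 tested introns, with a median log2 change of 4.64 over all tested introns. The intron of CQD1 (YPL109C, chromosome XVI, 345445 to 345596), whose product acts in coenzyme Q distribution, had 262 spliced and 59 unspliced reads over the WT libraries. In prp2-1 it had 0 spliced and 336 unspliced reads, a ratio at least 497-fold higher by the bound of 3 counts. In USV1 (YPL230W), which encodes a zinc finger protein, the unspliced percent rose from 45.2% ± 3.18 to 99.98% ± 0.0357 (SD, n = 3 libraries per group here and below). There were 3 spliced reads left in prp2-1, and the ratio was 3143-fold higher (95% counting interval 1071 to 15262). POP8 (YBL018C, chromosome II, 186353 to 186427), which encodes a subunit of RNase P, had 0 unspliced reads in WT and 163 in prp2-1. By the bound of 3 counts its ratio was at least 261-fold higher. SRC1 (YML034W, chromosome XIII, 211445 to 211570), which encodes an inner nuclear membrane protein, rose from 54.7% ± 4.13 to 99.97% ± 0.0342. NYV1 (YLR093C, chromosome XII, 327259 to 327399), a vacuolar SNARE gene, rose from 9.94% ± 0.505 to 99.5% ± 0.444. YML6 (YML025C, chromosome XIII, 225240 to 225338), a mitochondrial ribosomal protein gene, rose from 8.51% ± 0.484 to 99.1% ± 0.367. PAL2 (YHR097C, chromosome VIII, 298361 to 298484) rose from 7.79% ± 1.04 to 98.8% ± 0.419. IST1 (YNL265C, chromosome XIV, 145150 to 145254), an endosomal sorting gene, rose from 2.61% ± 1.78 to 95.8% ± 2.88. In the test, edgeR called 256 introns higher and 0 lower at an adjusted p under 0.05, and 0 were lower at an unadjusted p under 0.05. DESeq2 called 255 higher and 1 lower, and limma 260 higher and 1 lower. The lower one was YDR535C in both, which had no spliced read in any library. The 2 groups did not overlap in 252 introns, where chance gives 10%.

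**Figure D1:**
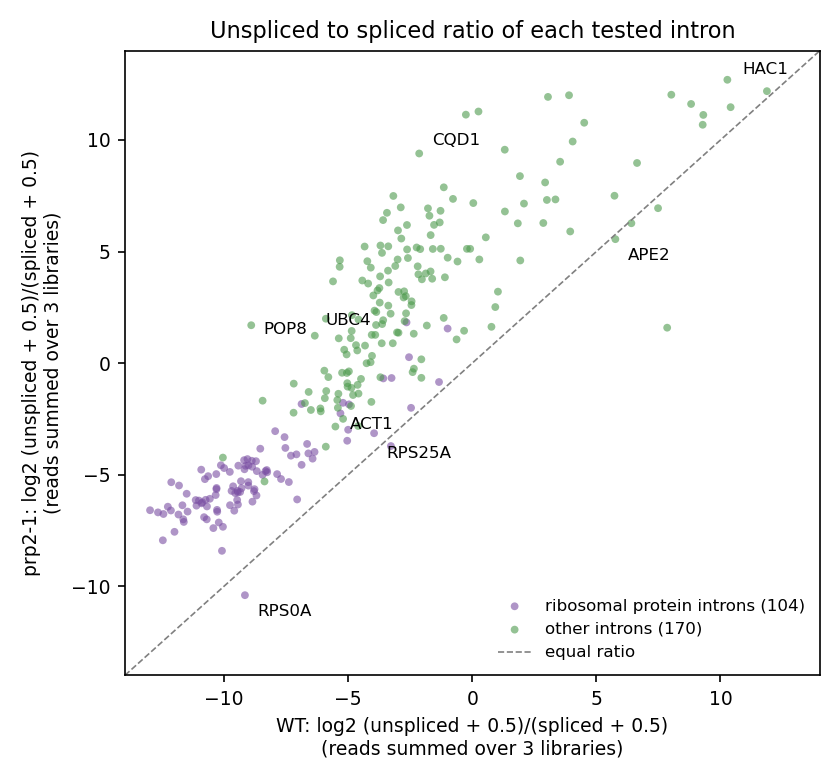
Each point is 1 of 274 tested introns, with the log2 ratio of unspliced to spliced reads (pseudocount 0.5, reads summed over 3 libraries) in WT on the x axis and in prp2-1 on the y axis; the dashed line marks an equal ratio. Nearly all points lie above the line, 256 of them past the test, and for the 8 introns with no spliced read, HAC1 among them, the place depends on the pseudocount.

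The introns of other well-studied genes covered a wide range. In ACT1 (YFL039C, chromosome VI, 54378 to 54686), the actin gene, the unspliced percent rose from 2.34% ± 0.386 to 19.9% ± 3.32, a log2 change of 3.37 (adjusted p = 1.65e-09, edgeR). COF1 (YLL050C, chromosome XII, 40222 to 40400), which encodes cofilin, rose from 2.16% ± 0.201 to 12.4% ± 2.65. The alpha-tubulin genes TUB1 (YML085C, chromosome XIII, 99260 to 99375) and TUB3 (YML124C, chromosome XIII, 23361 to 23658) rose from 2.77% ± 1.16 to 42.8% ± 2.93 and from 3.95% ± 0.325 to 34.1% ± 5.40. UBC4 (YBR082C, chromosome II, 407028 to 407122), a ubiquitin-conjugating enzyme gene, rose from 1.20% ± 0.0625 to 69.7% ± 3.15. GLC7 (YER133W, chromosome V, 432672 to 433196), which encodes the catalytic subunit of a protein phosphatase, rose from 13.9% ± 3.24 to 79.0% ± 2.32. Both introns of SUS1 (YBR111W-A, chromosome II), which acts in SAGA and mRNA export, rose. Intron 1 (462210 to 462289) went from 33.5% ± 1.86 to 96.3% ± 1.10 and intron 2 (462430 to 462499) from 17.8% ± 1.41 to 95.05% ± 2.61. The U3 small nucleolar RNA genes SNR17A and SNR17B rose from 7.38% ± 0.791 to 77.1% ± 1.33 and from 0.286% ± 0.0127 to 23.6% ± 3.18. This duplicated pair may share reads, and the counts of SNR17A differ between the full and the drawn tables. HAC1 (YFL031W, chromosome VI, 75840 to 76091), whose intron is removed by the tRNA ligase pathway and not by the spliceosome, had 0 spliced reads in both groups, so its ratio could not be compared. It had 1873 unspliced reads in WT and 2334 in prp2-1.

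The smallest change past the test among introns without overlap between the groups was in RPS25A (YGR027C), from 6.03% ± 0.185 to 10.3% ± 2.27 (log2 change 0.81). The ribosomal protein genes RPS8A (YBL072C) and RPL29 (YFR032C-A) changed by 1.56 and 1.67. TMH18 (YPR098C, chromosome XVI, 729386 to 729481) changed by 1.39, and SIM1 (YIL123W) by 1.61. SRB2 (YHR041C, chromosome VIII, 189750 to 189850), a Mediator subunit gene, changed by 1.67. URA2 (YJL130C), which acts in pyrimidine synthesis, changed by 1.73. Intron 1 of VMA9 (YCL005W-A, chromosome III, 107034 to 107110), a vacuolar ATPase subunit gene, changed by 1.74. The call of RPS25A was lost without WT replicate A, B or C (adjusted p = 0.0759, 0.0857 and 0.0706). Of the 18 introns that were not called, 8 had no spliced read in any library (HAC1, COX5B, YDR535C, YHL050C, YJR079W, YJR112W-A, YNL050C and YOR318C). The other 10 were ARF2, APE2, EFM5 intron 1, HMRA1 intron 1, MND1, PSP2, RPL18B, RPL34A, RPS0A and RPS22B intron 1. ARF2 had 1833 spliced reads in WT replicate B against 36 and 54 in A and C. In prp2-1 it had 488 in replicate B against 36 and 41. EFM5 intron 1 had 59 spliced reads in prp2-1 replicate B and 0 in A and C. RPS0A (YGR214W, chromosome VII, 920665 to 921119) had a log2 change of -0.95 (adjusted p = 0.218), which was 1.38 without WT replicate B (adjusted p = 0.112) and -1.60 without WT replicate C (adjusted p = 0.0387).

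The level reached in prp2-1 followed the level in WT. Of 95 introns under 1% unspliced in WT, 87 were of ribosomal protein genes, 94 were called higher, and the median in prp2-1 was 2.04%. The 86 introns at 1 to 10% in WT reached a median of 57.1%, with 84 called higher, and the 56 introns at 10 to 50% a median of 94.5%, with 54 called higher. The 37 introns over 50% in WT had a median of 99.9%, with 24 called higher. In prp2-1, 85 introns exceeded 90% unspliced, none of them (0) in a ribosomal protein gene, whereas 90 of 104 ribosomal protein introns stayed under 10%. The 3 ribosomal protein introns over 50% in prp2-1 were those of RPL2B and RPS27A and intron 2 of RPS22B. The spliced count of RPL2B differs between the full and the drawn counts, so its percent is uncertain. The log2 change itself did not rise or fall steadily with the WT level across all 274 introns (Spearman's rho = 0.05). Its median was 4.43 under 1% in WT, 5.09 at 1 to 10%, 5.87 at 10 to 50% and 3.44 over 50%. Within the 104 ribosomal protein introns it was smaller where the WT level was higher (rho = -0.74), and less so within the others (rho = -0.17). The change is relative to the WT ratio, so counting error in WT alone can make such a rho negative. Longer introns had smaller changes over the 246 introns with a position (rho = -0.41), less so within ribosomal protein introns (-0.27) and within the others (-0.18). These values are across introns, which are not independent replicates.

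Per library, the median unspliced percent over tested introns was 3.69% ± 0.115 in WT and 47.4% ± 6.21 in prp2-1 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries can give). For ribosomal protein introns the medians were 0.140% ± 0.00211 and 2.39% ± 0.738, and for all other introns 10.5% ± 0.410 and 91.1% ± 3.03. The share of all reads that was unspliced was lower, 1.81% ± 0.0802 and 9.14% ± 1.79, since ribosomal protein introns held 82.8% ± 0.732 and 85.7% ± 1.45 of the reads. The median log2 ratio of ribosomal protein introns minus that of the other introns was -6.33 ± 0.117 in WT and -8.71 ± 0.158 in prp2-1. This difference fell by 2.38 (exact permutation p = 0.1), more than the spread between replicates. In the set test of limma, camera, ribosomal protein introns did not pass the threshold (limma, adjusted p = 0.409). The unadjusted limma p was 0.119 and ranged from 0.0324 without prp2-1 replicate A to 0.415 without prp2-1 replicate B, and was 0.0467 without WT replicate C.

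**Figure D2:**
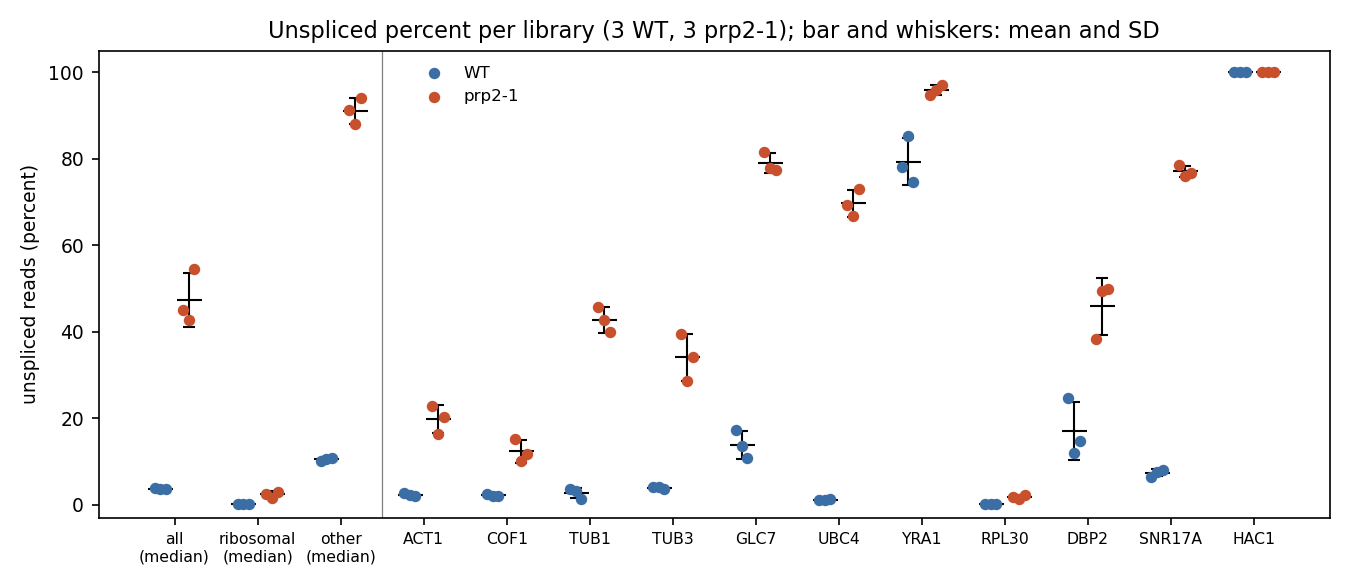
Points are single libraries, WT in blue and prp2-1 in red, and bars with whiskers are the mean and SD of 3 libraries; the y axis is the percent of reads that were unspliced, on the left as medians over tested introns and on the right for single introns. The prp2-1 libraries lie above all WT libraries in each set shown except HAC1, which was at 100% in both groups.

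The gene lists hold part of the targeted genes of each function, and their counts, ranges and medians cover the listed introns alone. Outside them are NYV1 and IST1 (log2 changes 10.73 and 9.92), which act in vesicle transport, YML6 and COX4 (10.25 and 7.88), of mitochondrial proteins, CQD1, MMS2 and POP8. NYV1, IST1 and YML6 changed more than the largest member of the list for their function, and for POP8, whose fold is a lower bound, this was not settled. All 15 tested introns of the vesicle transport list rose in prp2-1. They ranged from SEC17 (YBL050W, chromosome II, 125155 to 125270; log2 change 7.73), the alpha-SNAP gene, to YIP3 (YNL044W, chromosome XIV, 545292 to 545370; 2.33), whose spliced count differs between the full and the drawn tables. The adaptor gene APS3 (YJL024C, chromosome X, 396494 to 396570; 5.72) was the median member. All 11 tested introns of the RNA processing and export list rose. They ranged from the U1 snRNP gene MUD1 (YBR119W, chromosome II, 479346 to 479434; 8.87) to the helicase gene DBP2 (YNL112W, chromosome XIV, 414912 to 415913; 2.09), with TAD3 intron 1 (YLR316C, chromosome XII, 766182 to 766249; 5.96) in the middle. All 8 listed ubiquitin and proteasome introns rose. UBC5 (YDR059C, chromosome IV, 569634 to 569723) kept 1 spliced read in prp2-1, a ratio 749-fold higher (95% counting interval 114 to 30063), and the proteasome gene PRE3 (YJL001W, chromosome X, 435228 to 435343) changed by 5.74. UBC12 (YLR306W, chromosome XII, 744154 to 744287; 2.13) was the smallest, and its call was lost without WT replicate A or B (adjusted p = 0.0570 and 0.0926) or prp2-1 replicate A or C (0.0644 and 0.141). All 12 listed cytoskeleton introns rose. They ranged from YSC84 (YHR016C, chromosome VIII, 138241 to 138408; 7.65) to CIN2 (YPL241C, chromosome XVI, 96154 to 96233; 2.11), whose call was lost without WT replicate B (adjusted p = 0.111) or prp2-1 replicate A (0.0909) and with DESeq2. DYN2 intron 2 (YDR424C, chromosome IV, 1319618 to 1319697; 3.53), of a dynein light chain gene, had spliced counts that differ between the tables. Of 5 introns on the mitochondrial list 4 rose. Among these, MRPL44 (YMR225C, chromosome XIII, 721199 to 721345; 8.58) changed most and QCR10 (YHR001W-A, chromosome VIII, 107832 to 107894; 5.09) was the median member, while COX5B (YIL111W, chromosome IX, 155223 to 155310) had no spliced read.

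All 6 listed introns under feedback regulation rose. Of these, RPL30 (YGL030W, chromosome VII, 439094 to 439323) changed most (log2 change 3.58), RPL22B (YFL034C-A, chromosome VI, 64600 to 64920) by 2.60, and RPS14B (YJL191W, chromosome X, 73797 to 74204) least (2.03). In YRA1 (YDR381W, chromosome IV, 1236843 to 1237608), the mRNA export gene, the unspliced percent was already 79.3% ± 5.41 in WT and 95.9% ± 1.13 in prp2-1. Of 11 tested introns of genes that host small nucleolar RNAs 10 rose. This list was made by gene, so it holds both introns of RPL7A, RPL7B and RPS22B, whichever of them hosts the RNA. RPL7A intron 1 (YGL076C, chromosome VII, 365527 to 365985) changed by 6.07 and intron 2 (364965 to 365432) by 3.01. In its duplicate RPL7B (YPL198W, chromosome XVI) intron 1 (173163 to 173571) changed by 4.92 and intron 2 (173666 to 174072) by 3.04. NOG2 (YNR053C, chromosome XIV, 721771 to 722302; 3.77) was the median member, and RPS22B intron 1 (YLR367W; 0.51, adjusted p = 0.155) did not pass. Of 104 ribosomal protein introns 100 rose, by up to 6.75 in RPS18B (YML026C, chromosome XIII, 223381 to 223781), with RPS27B (YHR021C, chromosome VIII, 148117 to 148666; 3.77) as the median member. RPL18B, RPL34A, RPS0A and RPS22B intron 1 did not pass. Most ribosomal protein genes are duplicated, and values of single members of a pair are uncertain where reads are shared. Adjusted over the list alone, the counts were equal to those over all introns in each list. With camera no list (0) passed the threshold against the other introns (limma, lowest adjusted p = 0.409, or adjusted p = 0.840 with an estimated correlation). The lowest unadjusted limma p was 0.0572, for vesicle transport. By fry the introns of each of the 10 lists tested moved up on balance (highest adjusted p = 0.00049). Fry makes no comparison with other introns, and 256 of 274 tested introns rose, so this does not set the lists apart. Camera placed the ribosomal protein, meiosis, small nucleolar RNA host, feedback and other cell type lists below the other introns although their medians rose.

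The next comparisons took the unspliced and spliced reads apart, each relative to all targeted introns. Unspliced reads rose in 249 introns and fell in 6 (edgeR), with median log2 changes of 3.83 in ribosomal protein and 2.63 in other introns. POP8 rose from 0 to 163 reads, and RPS18B, RPL14A (YKL006W, chromosome XI, 432035 to 432432), SNR17B and RPL7A intron 1 rose by 7.05, 6.71, 6.70 and 6.28 on the log2 scale. Unspliced reads fell in HMRA1 intron 1, YDR535C, GCR1 (YPL075W, chromosome XVI, 412262 to 413012; log2 change -1.87), whose product activates glycolytic genes, RPS22B intron 1 (-0.91), RCF3 (YBR255C-A, chromosome II, 726918 to 727011; -0.86) and GIM4 (-0.70). The call of RCF3 was lost without WT replicate B or C (adjusted p = 0.0605 and 0.0673) or prp2-1 replicate A (0.0779). Spliced reads fell in 158 introns and rose in 17. In introns of other than ribosomal protein genes they fell in 142 and rose in 1, with a median log2 change of -2.67. The riser was the aminopeptidase gene APE2 (YKL157W, chromosome XI, 155272 to 155654; 0.64), which lost its call without WT replicate B (adjusted p = 0.0759). In ribosomal protein introns spliced reads rose in 16 and fell in 16 (median 0.02), a balance that rests on the scaling. Relative to all 13 tested introns that were over 98% unspliced in WT, which moved the median of all introns by -0.25, spliced reads of ribosomal protein introns rose in 1 and fell in 19 (median -0.25). The choice of such introns matters: relative to 5 of them (HAC1, COX5B, YJR112W-A, APE2 and YNL050C), picked without a set rule, all with higher fitted total reads in prp2-1 and 3 of them past the test, the counts were 0 and 61. Among the largest falls, CQD1 went from 262 to 0 spliced reads, USV1 from 2028 to 3, HMRA1 intron 1 from 16583 to 8, the kinase gene MRK1 (YDL079C, chromosome IV, 314045 to 314336) from 1403 to 4 and RRT8 (YOL048C, chromosome XV, 240948 to 241025) from 60 to 0. The largest rises under the first scaling were RPS10B (YMR230W, chromosome XIII, 732466 to 732875; 0.80), APE2, RPS25A (0.52), RPS7A (YOR096W, chromosome XV, 505938 to 506338; 0.49) and RPS0A (0.46).

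**Figure D3:**
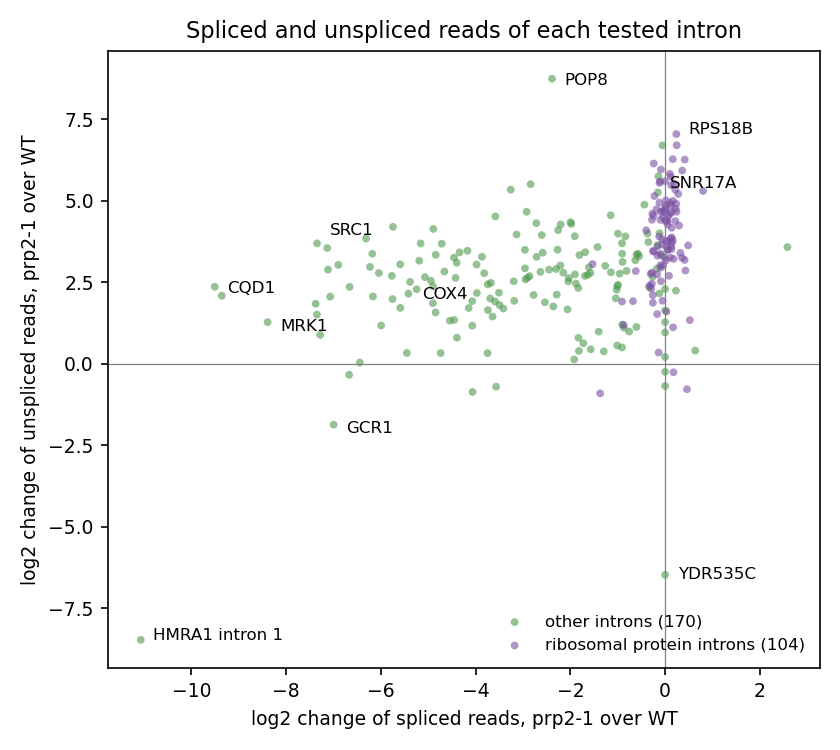
Each point is 1 tested intron, with the log2 change of its spliced reads (x axis) and of its unspliced reads (y axis) in prp2-1 over WT, ribosomal protein introns in purple and others in green. Ribosomal protein introns gather near 0 on the x axis (median 0.02 with TMM scaling, -0.25 when scaled by 13 mostly unspliced introns), other introns spread to the left (median -2.67), and introns with no spliced read are drawn at 0.

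Total reads per intron, spliced and unspliced together, rose in 54 introns and fell in 65 of 274 (edgeR). The largest rises were in the meiotic recombination gene REC114 (YMR133W, chromosome XIII, 537449 to 537564), from 4.81 ± 2.57 to 169 ± 75.3 CPM (counts scaled to a common library total), EFM5 intron 1 (YGR001C, chromosome VII, 497938 to 497999; log2 change 3.29), the ubiquitin conjugation gene MMS2 (YGL087C, chromosome VII, 346809 to 346893; 3.26), SRC1 (2.83) and the transcription regulator NCB2 (YDR397C, chromosome IV, 1266770 to 1266861; 2.75). The rise of EFM5 intron 1 rests on few WT reads, 3, 5 and 0 spliced and 5, 1 and 8 unspliced in replicates A, B and C. Intron 2 of EFM5 had no such rise. Its spliced reads were 214, 246 and 432 in WT and 212, 146 and 126 in prp2-1, and its unspliced reads 7, 4 and 3 against 56, 51 and 55. Total reads fell in MRK1 (-3.99), COX4 (YGL187C; -3.08), a cytochrome c oxidase subunit gene, and GCR1 (-2.59), and most in HMRA1 intron 1 and YDR535C. HMRA1 intron 1 (YCR097W, chromosome III, 293940 to 293993), in the copy of the mating type gene a1 at the silent locus HMR, which shares its sequence with the active copy of a cells, fell from 2781 ± 192 to 1.51 ± 1.53 CPM. YDR535C fell from 18.3 ± 5.03 to 0.148 ± 0.256 CPM. Total reads rose in 20 and fell in 11 ribosomal protein introns, a direction that turned relative to the 13 mostly unspliced introns (3 rose and 10 fell, with a shift of -0.29 over all introns). They rose in 34 and fell in 54 others (24 and 81 with that scaling).

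Among markers of another cell type or state, 14 meiosis introns were measured and 6 tested, of which 5 were spliced less completely in prp2-1. The checkpoint gene PCH2 (YBR186W, chromosome II, 602104 to 602216) was the median member (log2 change 4.38, from 18 to 3 spliced reads), and in REC114, the largest, the ratio was 444-fold higher (95% counting interval 55.6 to 19474, with 1 spliced read left in prp2-1), a call lost with the counts of 1 draw of 800000 reads. MND1 (YGL183C, chromosome VII, 157200 to 157282) did not pass (adjusted p = 0.366) with 2 and 1 spliced reads, and its log2 change of 1.94 was -0.89 without WT replicate C (adjusted p = 0.525). Total reads rose in 3 of the 6, and fell in none (0; edgeR). With HMRA1 intron 1 added, 5 of 7 rose in the ratio, and 3 rose and 1 fell in total reads. Of the 4 measured Mer1-dependent introns, which need a meiotic splicing factor, 1 was tested: REC107 (YJR021C, chromosome X, 469184 to 469263) went from 83.1% ± 8.50 to 99.6% ± 0.734 unspliced. HMRA1, the a1 marker, thus differed between the strains that every comparison here sets side by side.

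The last comparison followed the title's subject, selection bias, and asked which introns remain when a minimum number of reads is required at lower depth. With at least 10 spliced reads in every library, 147.8 ± 1.92 introns (mean and SD over 5 draws) were left at 200000 reads, 160 ± 1.00 at 400000 and 174.8 ± 2.17 at 800000, against 202 at full depth. At 200000 reads, 68.1% ± 0.947 of these were ribosomal protein introns, and their mean unspliced percent was 2.57% ± 0.208 in WT and 17.5% ± 0.449 in prp2-1. With at least 10 unspliced reads, 40.4 ± 2.30 introns were left at 200000 reads, 73.8 ± 2.05 at 400000 and 110.8 ± 2.86 at 800000, against 196 at full depth. At 200000 reads 13.9% ± 1.64 were ribosomal protein introns, with means of 45.5% ± 2.17 in WT and 75.4% ± 1.94 in prp2-1. With at least 10 reads of either kind, 209.6 ± 3.51, 234 ± 1.87 and 248.4 ± 1.14 introns were left, and the means at 200000 reads were 12.2% ± 0.705 and 39.0% ± 0.876. These averages depend on the rule. With a minimum of 10 on the mean over libraries in place of every library, ribosomal protein introns at 200000 reads made up 52.0% ± 0.520 of the introns with enough spliced reads and 33.5% ± 0.978 of those with enough unspliced reads. The means were then 5.69% ± 0.487 in WT and 33.1% ± 0.564 in prp2-1 for the former, and 20.6% ± 0.456 and 53.8% ± 0.942 for the latter. With at least 20 spliced reads in every library they were 1.76% ± 0.0754 and 12.7% ± 0.374. At 800000 reads the prp2-1 means were 25.2% ± 0.596 with enough spliced and 65.8% ± 0.380 with enough unspliced reads in every library, but 42.0% ± 0.283 and 48.3% ± 0.260 by the mean over libraries. Over all 274 tested introns at full depth, of which 38.0% were of ribosomal protein genes, the means were 17.6% and 49.6%. By the mean over libraries at 800000 reads both prp2-1 values lay below this 49.6%. At that depth and by that rule, introns with enough reads of either kind had a prp2-1 mean of 47.3% ± 0.133. The value for enough spliced reads lay below it and the value for enough unspliced reads above it. The ratio test called 211.2 ± 3.11 introns higher at 200000 reads, 231.6 ± 2.30 at 400000 and 242.2 ± 2.17 at 800000, of 235.8, 250.4 and 260.2 tested. RPS0A was called lower in 1 draw at 200000 and 1 at 400000 reads, and no intron (0, edgeR) in any draw at 800000. No test was made of these means, and the SD over draws does not reflect differences between cultures. The counts of 24 introns, 22 of them tested, differ between the drawn and the full tables.

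**Figure D4:**
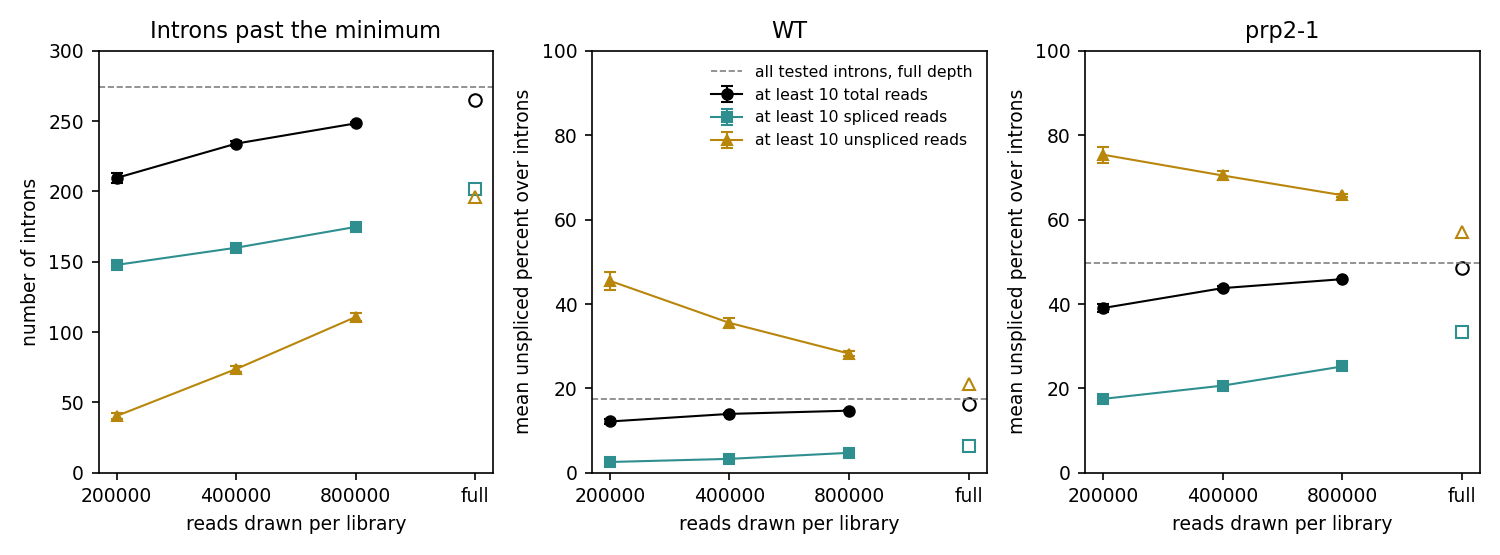
The number of introns with at least 10 total, spliced or unspliced reads in every library (left) and the mean unspliced percent over those introns in WT (middle) and prp2-1 (right) are plotted against the reads drawn per library; filled symbols are means of 5 draws with SD, open symbols the full table, and the dashed line all 274 tested introns. With the minimum in every library, introns with enough spliced reads had low unspliced percents (17.5% in prp2-1 at 200000 reads) and those with enough unspliced reads high ones (75.4%), a contrast that narrowed to 33.1% and 53.8% when the minimum applied to the mean over libraries.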

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

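All tests in this part were chosen after the result was seen. The table of random draws was not used for the main comparison, and at 800000 reads the counts of 24 of 309 introns differed from those in the full table by over 1.5-fold and beyond sampling noise (z over 5), 17 by their spliced and 9 by their unspliced reads. Spliced reads of EFB1, for example, were 42528 over the 6 libraries (mean of 5 draws) where 72112 would follow from the full table, and those of SAR1 were 466 against 25.1. DYN2 intron 1 had 14.4 spliced reads in the draws and 0 in the full table. In groups of 3 libraries no single library was tested for standing apart.

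The tables argue against random sampling of reads as the source, which forbids a draw with more reads than the full table, yet 211 of 9270 entries at 800000 reads held more, 129 of them in 15 of the 24 introns. Under random sampling, introns chosen on 1 draw would seldom differ again in the others, yet of the introns chosen on each draw at least 88.5% differed again, the same way, in the mean of the other 4 draws. Reads shared between partner genes, whose symbols differ only in a last A or B, cannot be the whole source. Of the 24 introns, 10 (41.7%) have no such partner among the targeted genes. The sum over both partners was within 1.5-fold in 9 of 14 cases. Duplicates with other names or without a targeted intron were not covered. A processing step that depends on the reads supplied to it may account for part: in 4 of the 17 introns with differing spliced reads, 23.5% (exact 95% interval 6.81 to 49.9), the variance over the mean between draws of a library was above 10 (ARF2 106, DYN2 intron 2 720, SAR1 650 and SNR17A 6372), against 0 of the introns that did not differ. That share cannot be told apart from the bound of 25% set for this explanation, and it would be 26.7% over the 15 introns with a mean of 10 reads in a library, so it stays open, as does a fixed difference between the tables for the other 13. No biological explanation was tested, since both tables come from the same libraries; without the differing introns, 235 introns were called higher in the ratio test.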

How the results depend on the processing

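The alternatives added after seeing the data are those named as such among the processing steps. Among the named introns no call reversed under the alternatives checked for them (RPS0A and MND1, not called, changed sign without 1 WT library). These checks left out the scalings by mostly unspliced introns. Counts of calls were compared by size alone, which cannot show a reversal. With those scalings the balance of rises and falls of ribosomal protein introns changed for spliced reads and turned for total reads. In all, 56 values moved beyond the spread between replicates (between draws, for averages at lower depth) or 1.5-fold. The ratio test called between 183 (at least 10 unspliced reads in every library, which leaves fewer introns to test) and 263 introns, 252 to 258 when 1 library was left out; DESeq2 shared 254 of the 256 calls, and limma added 6 calls, or 9 with a pseudocount of 5 (MND1 among them). One that limma added, COX5B, has no spliced read, so its call depends on the pseudocount. Total reads gave 81 to 127 calls, unspliced reads 251 to 258 and spliced reads 148 to 169 without 1 library. The difference in median unspliced percent (43.7 points; 40.2 to 46.1 without 1 library) was 31.9 as a mean over introns, 7.33 over pooled reads, 54.4 without a minimum, 33.9 with a mean of 100 reads, 63.2 with at least 10 unspliced and 16.6 with at least 10 spliced reads in every library, which follows from the introns left. The difference between ribosomal protein and other introns (-2.38; -2.47 to -2.31 without 1 library) was -1.89 with a pseudocount of 5, -78.4 points on the percent scale and -1.55 without a minimum; the cause was not tested. Its camera p ranged from 0.0324 to 0.415. The test of gene lists with camera called 0 lists in each library left out, whereas fry, which asks another question, called 10. At 200000 reads, introns with enough unspliced reads numbered 70 with a minimum of 5, 22.6 with 20 and 154.4 when the minimum applied to the mean over libraries; at 400000 reads they numbered 42.8 with 20 and 201.6 by the mean, and at 800000 reads 233.4 by the mean, by construction of the minimum. The averages over the introns left moved with it. At 200000 reads, minimums of 5 and 20 and the mean over libraries gave, for spliced reads, ribosomal shares of 63.3%, 73.8% and 52.0% (67.0% to 68.1% without 1 library), WT means of 3.28%, 1.76% and 5.69% and prp2-1 means of 20.6%, 12.7% and 33.1% (17.2% to 18.7%). For unspliced reads they gave shares of 16.1%, 14.1% and 33.5%, WT means of 37.0%, 50.5% and 20.6% and prp2-1 means of 70.5%, 76.6% and 53.8%, and for reads of either kind WT means of 14.01%, 9.75% and 14.6% and prp2-1 means of 43.6%, 33.7% and 44.1% (38.1% to 40.3%). At 800000 reads the prp2-1 means were 29.4%, 21.2% and 42.0% for spliced (24.7% to 27.2%) and 60.2%, 69.0% and 48.3% for unspliced reads (64.8% to 66.5%). Leaving out introns with no spliced read changed the rho with the WT level from 0.05 to 0.14 and with total reads from -0.18 to -0.26. Whether the replicate letters pair the libraries is not settled, and the libraries were taken as unpaired: same-letter correlations of the ratio were 0.09, 0.20 and 0.27 over all tested introns, not all above 0.1, but 0.12, 0.13 and 0.20 at a mean of 100 reads, and 0.28, -0.06 and 0.02 for total reads. In the ratio each library correlated best with its own letter, a hint from the data and not from the labels. With a block for the letter the ratio test gave 258 calls, total reads 121, unspliced reads 254 and spliced reads 174. The ribosomal protein difference was then -2.38 (exact sign-flip p = 0.25, the smallest that 3 pairs can give). Small changes may be missed: on simulated counts with a fixed dispersion, a 2-fold change of the ratio was recovered in 46.3% of introns. That simulation did not use the spread of these libraries, so the share recovered here may differ.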

Other observations

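The tests on HMRA1, on the spliced and unspliced reads of ribosomal protein introns, on depth within each class and on 5′ splice sites outside ribosomal protein genes, without HAC1 or without introns that lack spliced reads were chosen after the result was seen; the other tests of this part were planned. In genes with a pair of tested introns, the changes were 5.71 and 6.55 in SUS1, 5.10 and 6.48 in YOS1, 1.74 and 3.93 in VMA9, 6.07 and 3.01 in RPL7A, 4.92 and 3.04 in RPL7B, 0.51 and 2.82 in RPS22B, and 1.94 and 4.35 in EFM5 on the log2 scale (intron 1, then intron 2). The value of EFM5 intron 1, which was not called, rests on prp2-1 replicate B, with 59 spliced reads against 0 in A and C. The median difference within these 7 genes was 2.19, against 1.82 for random pairs of introns of the same class. A share of 0.672 of 10000 random sets of pairs had as small a median, so the test gave no sign that introns of a gene share their change.

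Of the 246 tested introns with a position, 189 began with GTATGT and 57 with another 5′ splice site, HAC1 among the latter although the spliceosome does not remove its intron. Their median unspliced percents in WT were 3.24% and 6.86%, a difference that did not pass (permutation p = 0.0518, 100000 resamples; 0.141 without HAC1, with a median of 5.87% for other sites). Outside ribosomal protein genes the 122 introns with GTATGT had a median of 7.42% in WT and the 34 with another site 42.8% (permutation p = 3.0e-05), or 36.8% for 33 without HAC1 (permutation p = 2.0e-05). The size of this difference rests in part on introns with no spliced read in any library, 5 of which have another site (COX5B, HAC1, YHL050C, YJR079W and YNL050C) and 1 GTATGT (YJR112W-A). Without them the medians outside ribosomal protein genes were 7.39% for 121 and 24.5% for 29 introns (permutation p = 0.00104), and over all introns 3.23% and 4.31% (permutation p = 0.446). Outside ribosomal protein genes other sites may thus be spliced less completely in WT. The median log2 changes in prp2-1 were 4.80 and 4.51 (permutation p = 0.387), and 5.55 and 5.12 outside ribosomal protein genes (permutation p = 0.376). Without introns that lack spliced reads they were 4.80 and 4.77 (permutation p = 0.877), and 5.56 and 5.24 (permutation p = 0.585), none of which passed. These are values across introns, which are not independent replicates.

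Reads of HMRA1 intron 1 were 2101-fold lower in prp2-1 than in WT at equal library totals (95% counting interval 1106 to 4595). Lower depth is argued against, since the prp2-1 libraries held 1.11 times the reads of the WT libraries. A fall of spliced reads alone is also argued against, since unspliced reads fell as well (log2 change -8.47, from 448 to 1), while those of 249 other introns rose. Loss through the splicing block is argued against too, since the lowest other intron with spliced reads and over 100 unspliced reads in WT, GCR1 (-1.87), lies 6.60 above it; YDR535C, which fell from 115 to 1 read, had no spliced read in any library. A different mating type of the 2 strains is a candidate explanation, with which the joint fall is consistent, but the labels used here give no mating type, so it remains a hypothesis.

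The log2 change of the ratio was smaller in ribosomal protein introns than in other introns by 1.59 in medians. Their unspliced reads did not rise less but more, by 1.20 in medians, and their spliced reads changed less, with a median higher by 2.69. Both follow largely from the WT levels. Ribosomal protein introns went from a median of 0.140% to 2.39% unspliced, which leaves little room for a fall of spliced reads at a given total. The other introns went from 10.5% to 91.1%, which limits the rise of unspliced reads and forces a fall of spliced reads. The split into 2 kinds of read therefore cannot locate the difference or give a reason for it. For higher depth of these introns the values go both ways. Matched to other introns within 1.5-fold of the mean total reads, the difference shrank to -0.28 over 102 ribosomal protein and 34 other introns. This met the prediction for depth that was fixed beforehand. A change that falls with depth, a condition added later, is argued against within ribosomal protein introns (rho = 0.33, bootstrap 95% interval 0.15 to 0.49). It was not seen within the others (rho = -0.03, -0.19 to 0.13). Depth, and expression level with it, therefore stays open.

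With the 6 libraries in 2 groups of 3 there are 10 splits, too few for a share under 0.05; the real one was the 1 split with as many calls. It gave 256 calls for the ratio, 119 for total reads, 255 for unspliced reads and 175 for spliced reads, and the highest other split gave 0 in each. Every other split mixed the genotypes within its groups, so the difference between them counted as spread within groups. The 0 calls there do not measure how often chance gives calls.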
